A study of Mus musculus with 2 samples.

How the data were processed

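Single-cell RNA sequencing was done on tumours taken from livers of mice of 2 genotypes, Crtc2+/+ and Crtc2-/-, with 1 library per genotype. The number of animals and tumours pooled per library is not given in the sources used here. Per the labels' protocols, cells were loaded on a 10x Genomics Chromium controller, and libraries were made with 3' chemistry and sequenced on an Illumina HiSeq 2000. The protocols name a v2 reagent kit. Deposited values were raw UMI counts per gene and barcode, 1 matrix per library, written by Cell Ranger 7.1.0 per the file headers. Per the submitters' processing notes, the genome build was mm10 and Cell Ranger and Seurat were used, with no Seurat version and no account of what Seurat did. Whether intronic reads were counted and which gene annotation was used are not given in the sources used here. No barcode had fewer than 501 UMIs in the Crtc2-/- or 502 in the Crtc2+/+ matrix, so barcodes had been filtered before deposit and empty droplets could not be read.

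The matrices held 32285 features each, of which 32158 (99.6%) matched gene identifiers of GENCODE release M21 (GRCm38), the source of the coordinates. Features that shared a symbol, 78 in number, were kept apart by identifier. The Crtc2+/+ library held 9707 barcodes with a median of 7195 UMIs and 2662 genes, and the Crtc2-/- library 9242 barcodes with 6688 UMIs and 2549 genes. Barcodes were kept with at least 500 UMIs, at least 250 genes and at most 20% mitochondrial UMIs, which left 9612 and 9174. Doublets were called in each library by Scrublet (in scanpy 1.11.5) at an expected rate of 0.8% per 1000 cells, 7.69% and 7.34%, on genes seen in at least 3 cells. It called 285 (2.97%) and 273 barcodes (2.98%), below the expected rate. These were removed, and doublets it missed remain among the cells. Kept were 9327 Crtc2+/+ and 8901 Crtc2-/- cells, with median depths of 7098 and 6560 UMIs and median mitochondrial shares of 1.85% and 2.24%.

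Both libraries were clustered together without integration. Counts were scaled to 10000 per cell and log-transformed, 2000 variable genes were chosen per library, values were scaled to unit variance and limited to 10, and 30 principal components, 15 nearest neighbours and Leiden clustering at resolution 1 with 5 iterations were used (leidenalg 0.10.2, scikit-learn 1.9.0, anndata 0.12.19). Other tools were Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9. Clusters were named from fixed markers of 17 classes. For each gene the log2 ratio of the cluster's CPM over the median CPM of all clusters was taken, with 10 CPM added to each. A class was a candidate with at least 3 markers at a log2 ratio of at least 1 and present in at least 10% of cells, and the candidate with the highest mean log2 ratio over its markers gave the name. A cluster stayed unnamed where another class had more markers among its 10 most enriched genes. The marker genes were fixed beforehand, but this scoring rule, including the median over clusters as the baseline, was set after seeing the data, because macrophage-like cells dominated a baseline of all other cells. Unnamed clusters held 0 of 9327 Crtc2+/+ cells and 10.99% of Crtc2-/- cells. All class names mean cells like that type by transcripts, since no cell was sorted.

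Comparisons were made within the 10 classes that had at least 50 cells in each library. Because each genotype had 1 library and cells of 1 library are not replicates, no test, p-value or count of changed genes was made. Raw counts were summed per library and class and given as CPM of the class total with exact 95% Poisson intervals. Log2 ratios were Crtc2-/- over Crtc2+/+ after adding 10 CPM. Ratios of Crtc2 and of its related genes carry the exact conditional interval of a ratio of Poisson sums. Class shares carry exact 95% Clopper-Pearson intervals, and log2 ratios of shares an interval from the normal approximation. Where one sum was 0, a fold is a lower bound against a floor of 3 counts. The median log2 ratio of a gene list used members with at least 20 UMIs over both libraries and was placed among 10000 random lists of equal size, matched on mean CPM in 20 bins, which describes these libraries only. Limits of list medians came from resampling members. Shares of T cell-like cells with a UMI of a state gene were read after thinning each cell to 1000 UMIs without replacement.

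Genes were named by a rule. In the 4 classes with the most cells in their smaller library, and in hepatocyte-like cells, it took the 5 highest and the 5 lowest log2 ratios. Eligible genes had at least 50 CPM in a library, a UMI in at least 5% of cells of the higher library, and a CPM there of at least 20% of the highest CPM in any other class, against free RNA. Mitochondrial, ribosomal protein, haemoglobin, variable segment, sex-linked and predicted genes were left out. Crtc2, Crtc1, Crtc3, Creb1, Prkdc, the T cell state genes and up to 4 members of each list with the largest ratios were also named. Of these genes, 2 are not reported here. The rule, gene lists, markers, filters and first alternatives were written before the data were examined.

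The 38 gene lists were written from general knowledge. Read first in hepatocyte-like cells were CREB and CRTC target genes, gluconeogenesis, fatty acid synthesis, lipid droplet and steatosis, cholesterol synthesis, fatty acid oxidation and PPAR alpha targets, bile acid synthesis and transport, cytochrome P450 of mature hepatocytes, liver tumour and fetal genes, Wnt and beta-catenin liver targets, acute phase, NRF2 targets and p53 targets. Read first in macrophage-like cells were MHC class II presentation, inflammatory cytokines and chemokines, lipid-associated macrophage, resident Kupffer cell and immune suppression by myeloid cells. Read first in T cell-like cells were T cell exhaustion and activation, cytotoxic effector, naive and memory T cell and regulatory T cell. Sinusoidal endothelial identity and capillary and tumour endothelium were read in endothelial-like cells, and extracellular matrix was meant for mesenchymal-like cells. CRTC and CREB family and regulators, non-homologous end joining, homologous recombination, type I interferon response, cytosolic DNA sensing, interferon gamma response, MHC class I presentation, proliferation, endoplasmic reticulum stress, tissue dissociation and heat shock, hepatocyte free RNA, mitochondrially encoded and sex-linked were read in all compared classes.

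Alternatives were mitochondrial limits of 10% and 50%, at least 1000 UMIs, called doublets kept, Leiden resolutions 0.5 and 2, each library clustered and named on its own, a denominator without hepatocyte-like cells, median-ratio size factors, a pseudocount of 1 CPM, subtraction of free RNA, means of per-cell CPM, list members with at least 100 UMIs, and thinning to 2000 UMIs or none. Free RNA was modelled as the library's summed profile, scaled so that hepatocyte markers reached 0 in T cell-like cells (5.02% and 3.44% of their UMIs). Chosen after seeing the data were a denominator without macrophage-like and unnamed cells, clusters with at least 10% of their cells from each library, and unnamed cells counted as macrophage-like. Ranking, intervals and list percentiles were tested on simulated data, with Poisson counts at the depths of T cell-like, macrophage-like and hepatocyte-like cells. All 200 genes changed 2-fold or 4-fold ranked first with the right direction, and the intervals covered the true value in 94.7% to 95.7% of genes. Since the counts were drawn as Poisson, as the intervals assume, this coverage was given by construction. Of 300 lists of 12 unchanged genes, 2.67% to 6.33% fell outside the central 95%. The simulation held no biological spread between cells or between animals.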

Results

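Single-cell transcriptomes were measured in liver tumours of 2 mouse genotypes, Crtc2+/+ and Crtc2-/-, with 1 library each. Crtc2 encodes a coactivator of the transcription factor CREB. Diethylnitrosamine (DEN), a liver carcinogen, was given intraperitoneally at 25 mg/kg when mice were 2 weeks old, and a diet that produces non-alcoholic steatohepatitis (NASH) was fed from week 8 to week 26. The Crtc2+/+ library held 9707 barcodes and 81487425 UMIs (unique molecular identifiers), and the Crtc2-/- library 9242 barcodes and 78040008 UMIs. Median depth per barcode was 7195 and 6688 UMIs. After filters and doublet removal, 9327 Crtc2+/+ and 8901 Crtc2-/- cells were compared. The comparison asked how tumour, stromal and immune cells of these tumours differed with Crtc2 genotype. With 1 library per genotype, no difference has a replicate check, no test was made, and genotype cannot be separated from the animal or tumour sampled. Intervals are 95% intervals and cover counting error only. Values are given for the Crtc2+/+ and then the Crtc2-/- library, in CPM (UMIs of the gene scaled to the total of the class), and log2 ratios are Crtc2-/- over Crtc2+/+ after adding 10 CPM.

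Crtc2 transcripts were fewer in the Crtc2-/- library but were still detected. Over all kept cells, Crtc2 (ENSMUSG00000027936, protein-coding, GRCm38 chromosome 3, 90254163 to 90264125, plus strand) was counted 613 and 400 times, 7.97 (7.35 to 8.63) and 5.43 (4.91 to 5.99) CPM, a Crtc2-/- to Crtc2+/+ ratio of 0.681 (0.599 to 0.774). The ratio was 0.301 (0.163 to 0.553) in B cell-like, 0.465 (0.332 to 0.647) in T cell-like, 0.469 (0.315 to 0.695) in conventional dendritic-like and 0.631 (0.419 to 0.942) in monocyte-like cells. In macrophage-like cells it was 1.001 (0.780 to 1.27), from 305 and 88 UMIs. In hepatocyte-like cells it was 0.550 (0.233 to 1.25), from 17 and 11 UMIs, an interval that includes 1. Which part of the gene was deleted is not stated in the sources used here, and 3' tags that lie outside a deleted part do not test the genotype label. The paralogues Crtc1 and Crtc3 had ratios of 1.08 (0.953 to 1.22) and 1.24 (1.19 to 1.28) over all kept cells. Creb1, the partner transcription factor, had a ratio of 1.09 (1.06 to 1.12), and Prkdc, which encodes the catalytic subunit of DNA-dependent protein kinase, 1.10 (1.04 to 1.15). These ratios over all cells also carry the different cell mixtures of the libraries: within T cell-like cells Crtc3 was at 1.03 (0.949 to 1.12) and Prkdc at 0.891 (0.804 to 0.988).

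**Figure D1:**
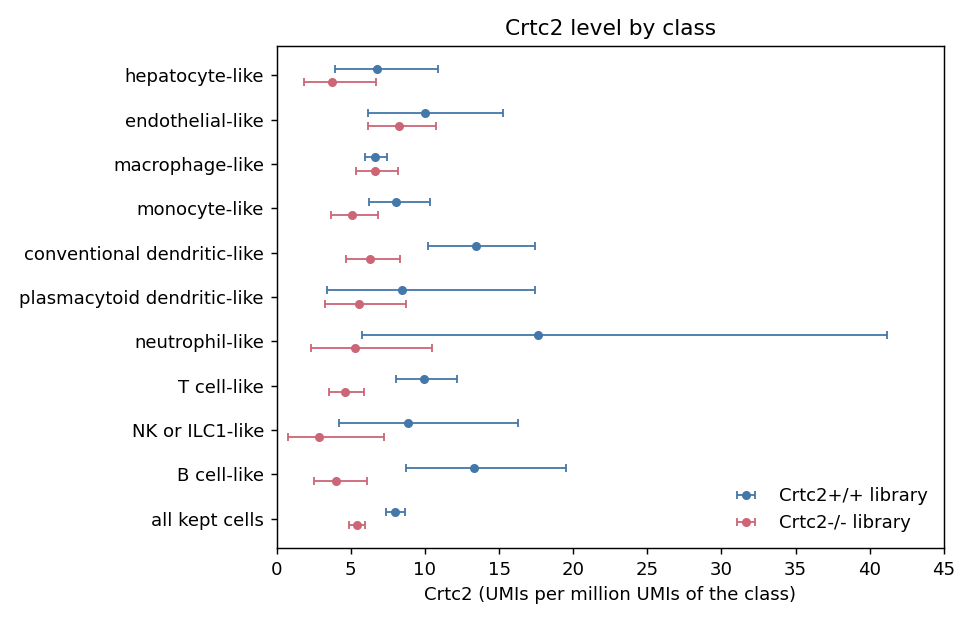
Crtc2 level per class in CPM (x axis), one point per library with its exact 95% Poisson interval. Over all kept cells the Crtc2+/+ point was at 7.97 and the Crtc2-/- point at 5.43, while the macrophage-like points were at 6.66 and 6.66.

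Macrophage-like cells made up 49.9% (48.8 to 50.9; 4651 cells) and 9.53% (8.92 to 10.2; 848 cells), a share 5.23-fold lower in the Crtc2-/- library, with a log2 ratio of -2.39 (-2.48 to -2.29). Most other classes held a larger share of that library. Neutrophil-like cells made up 1.07% (0.873 to 1.30; 100 cells) and 4.56% (4.14 to 5.02; 406 cells), log2 ratio 2.09 (1.78 to 2.40), and plasmacytoid dendritic-like cells 0.965% (0.777 to 1.18; 90 cells) and 3.76% (3.38 to 4.18; 335 cells), 1.964 (1.63 to 2.30). Endothelial-like cells made up 2.57% (2.26 to 2.92; 240 cells) and 6.62% (6.11 to 7.15; 589 cells), 1.36 (1.15 to 1.58), and B cell-like cells 5.63% (5.17 to 6.12; 525 cells) and 12.8% (12.1 to 13.5; 1138 cells), 1.18 (1.04 to 1.33). Conventional dendritic-like cells stood at 3.90% (3.52 to 4.32; 364 cells) and 7.40% (6.87 to 7.97; 659 cells), 0.92 (0.74 to 1.10). T cell-like cells made up 20.6% (19.8 to 21.5; 1923 cells) and 28.1% (27.2 to 29.04; 2501 cells), 0.45 (0.37 to 0.52), monocyte-like cells 9.09% (8.52 to 9.69; 848 cells) and 10.7% (10.1 to 11.4; 953 cells), 0.24 (0.11 to 0.36), and NK or ILC1-like cells 2.35% (2.05 to 2.68; 219 cells) and 2.86% (2.53 to 3.23; 255 cells), 0.29 (0.03 to 0.54). Hepatocyte-like cells, which can include tumour hepatocytes, made up 3.47% (3.11 to 3.87; 324 cells) and 2.56% (2.24 to 2.91; 228 cells), -0.44 (-0.68 to -0.20). Of the Crtc2+/+ hepatocyte-like cells, 46.9% were in cluster 26, whose most enriched genes partly overlapped those of cholangiocyte-like cells. Cholangiocyte-like cells, 43 and 11, were too few to compare. Clusters without a class name held 0 of 9327 Crtc2+/+ cells (0% to 0.0395%) and 10.99% (10.3 to 11.7; 978 cells) of Crtc2-/- cells.

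Shares of the same total constrain each other. Without macrophage-like and unnamed cells in the denominator, a setting chosen after seeing the data, T cell-like cells made up 41.1% and 35.3%, monocyte-like cells 18.1% and 13.5% and NK or ILC1-like cells 4.68% and 3.60%, all lower in the Crtc2-/- library. Endothelial-like (5.13% and 8.33%), conventional dendritic-like (7.78% and 9.31%), plasmacytoid dendritic-like (1.92% and 4.73%), neutrophil-like (2.14% and 5.74%) and B cell-like shares (11.2% and 16.1%) stayed higher by that denominator. With unnamed cells counted as macrophage-like, macrophage-like cells made up 49.9% and 20.5%. The hepatocyte-like share was higher in the Crtc2-/- library, 1.74% and 2.57%, when each library was clustered on its own. Macrophage-like cells of the Crtc2+/+ library lay mostly in cluster 0 (2695 and 28 cells) and those of the Crtc2-/- library mostly in cluster 8 (148 and 563 cells). A cluster held mostly by 1 library may be that library rather than a cell type.

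**Figure D2:**
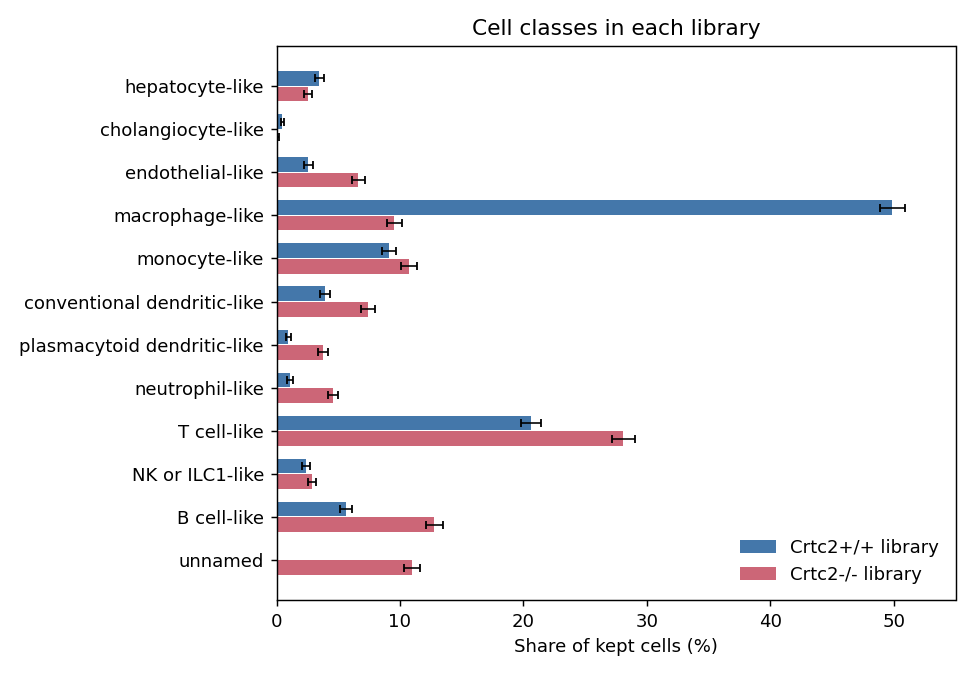
Share of kept cells in percent (x axis) for each class, one bar per library with its exact 95% Clopper-Pearson interval. Macrophage-like cells stood at 49.9% in the Crtc2+/+ and 9.53% in the Crtc2-/- library, and unnamed cells at 10.99% in the Crtc2-/- library.

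T cell-like cells of the Crtc2-/- library expressed more Ccl4, Nr4a2, Tox2, Nr4a3 and Lag3 and less of the interferon-stimulated genes Ifit3, Usp18, Rsad2 and Ifit1. Ccl4, a chemokine of activated T cells, was at 219.5 (210.2 to 229) and 1155 (1137 to 1173) CPM (log2 ratio 2.34), and Nr4a2, a nuclear receptor induced by antigen receptor signals, at 51.5 (47.1 to 56.3) and 284 (275 to 293) CPM (2.26). Tox2, Nr4a3 and the inhibitory receptor gene Lag3 were at 5.23 and 54.5, 30.5 and 147 and 13.6 and 70.6 CPM. In the other direction, Ifit3 was at 279.6 (269 to 290.4) and 40.1 (36.7 to 43.6) CPM (-2.53). Usp18, Rsad2 and Ifit1, which are also induced by interferon, were at 134 and 21.1, 98.6 and 14.6 and 168 and 32.9 CPM. Cdh1, which encodes E-cadherin, was at 55.6 and 4.54 CPM. These 10 genes were picked by a fixed rule of size among 3436 eligible genes. Of the exhaustion and activation genes, 13 of 14 measured members were above 0, with a median log2 ratio of 1.498 and a percentile of 100 among 10000 random lists matched on expression. Ccl3 (50.1 and 331 CPM) had the largest ratio of the list, and Pdcd1, which encodes PD-1, was at 75.1 and 206 and Tox at 831 and 1610.5 CPM.

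Effector genes were also somewhat higher. Of the cytotoxic effector genes, 12 of 14 were above 0 (median 0.24, percentile 99.93). Granzyme A, Gzma, was at 65.3 and 209 CPM, interferon gamma, Ifng, at 39.9 and 91.96, and Ctsw, lower, at 352 and 214. Naive and memory T cell genes had a median of 0.22 (percentile 99.5; 8 of 10 above 0), with Slamf6 at 63.7 and 135 and the survival gene Bcl2 at 1435 and 829 CPM. Regulatory T cell genes had a median of 0.46 (percentile 100; 8 of 11 above 0), with Ctla4 at 103 and 345 and Izumo1r at 30.9 and 70.4 CPM. That median was 0.25 as a mean of per-cell CPM and 0.84 with a pseudocount of 1 CPM. Foxp3, which encodes the defining factor of these cells, was at 21.1 and 20.8 CPM. In T cell-like cells the dissociation and heat shock genes had a median of 0.38, and hepatocyte transcripts, read as markers of free RNA, a median of 0.29. Both libraries contributed to each of the 8 T cell-like clusters, but cluster 23 held 248 Crtc2+/+ and 28 Crtc2-/- cells and cluster 18 held 85 and 337. Exhaustion and activation genes had a median above 0 in 7 of the 8 clusters, with a range of -0.56 to 1.23.

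More T cell-like cells of the Crtc2-/- library carried Pdcd1, Lag3, Havcr2 and Tox transcripts at equal depth. After each cell was thinned to 1000 UMIs, a Pdcd1 UMI was seen in 7.17% (6.06 to 8.42) and 15.99% (14.6 to 17.5) of T cell-like cells, a Lag3 UMI in 1.68% (1.15 to 2.36) and 6.01% (5.11 to 7.02), a Havcr2 UMI in 0.681% (0.363 to 1.16) and 3.49% (2.80 to 4.28) and a Tox UMI in 42.7% (40.5 to 44.98) and 58.3% (56.4 to 60.3). In B cell-like cells, which should lack these transcripts, the thinned shares were 0% and 0.176% for Pdcd1, 0% and 0% for Lag3, 0.382% and 0.0880% for Havcr2, and 0% and 0.792% for Tox. CD8 transcripts (Cd8a or Cd8b1) were seen in 32.04% (29.95 to 34.2) and 40.8% (38.8 to 42.7) and Ifng in 3.93% (3.10 to 4.90) and 7.49% (6.49 to 8.60). Gzmb was seen in 12.9% and 16.6% and Gzmk in 14.9% and 16.4%. Cd4 (5.39% and 5.05%), Tcf7 (12.2% and 12.7%), Mki67 (1.88% and 2.65%) and Foxp3 (2.62% and 1.68%) differed by less than 1 point. Median depth was 4500 and 4572 UMIs in T cell-like and 3407 and 3920 in B cell-like cells, and 13 and 6 T cell-like cells were too shallow to thin.

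Without thinning, the shares of T cell-like cells with a UMI were 18.4% and 36.5% for Pdcd1, 5.51% and 20.03% for Lag3, 2.91% and 12.2% for Havcr2 and 71.1% and 82.2% for Tox. They were 50.2% and 59.3% for Cd8a or Cd8b1, 12.9% and 22.7% for Ifng, 26.99% and 33.03% for Gzmb and 32.5% and 38.02% for Gzmk. Unthinned shares were 14.6% and 15.5% for Cd4, 40.4% and 37.1% for Tcf7, 6.08% and 8.96% for Mki67 and 5.15% and 4.84% for Foxp3.

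Type I interferon response genes were lower in the Crtc2-/- library in most classes. All 21 measured members were below 0 in T cell-like cells (median -1.32, percentile 0) and all 21 in NK or ILC1-like cells (median -1.41, percentile 0). Oasl2 was at 80.9 and 4.69 CPM in T cell-like cells, and Isg15 at 212 and 27.000 and Ifit1 at 126 and 7.11 CPM in NK or ILC1-like cells. The medians were -0.79 in hepatocyte-like, -0.78 in conventional dendritic-like, -0.76 in plasmacytoid dendritic-like, -0.69 in monocyte-like, -0.59 in macrophage-like, -0.57 in endothelial-like and -0.27 in neutrophil-like cells. Each of these 9 medians lay below the central 95% of random lists. In B cell-like cells the median was 0.01, with 9 of 18 members above 0. Within T cell-like cells the median was below 0 in 7 of 8 clusters, with a range of -1.64 to 0.19. Macrophage-like clusters were divided, 3 below and 3 above 0 (-0.94 to 0.07), and the median was -0.19 in those that both libraries shared and -0.98 with unnamed cells counted as macrophage-like. In endothelial-like cells it was 0.49 in cluster 12, which held 77.6% of the Crtc2-/- cells, and -0.42 in cluster 20. As a mean of per-cell CPM the endothelial-like median was -0.38, and in monocyte-like cells it was -0.31 with a mitochondrial limit of 10%. In neutrophil-like cells it was -0.04 after subtraction of free RNA.

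**Figure D3:**
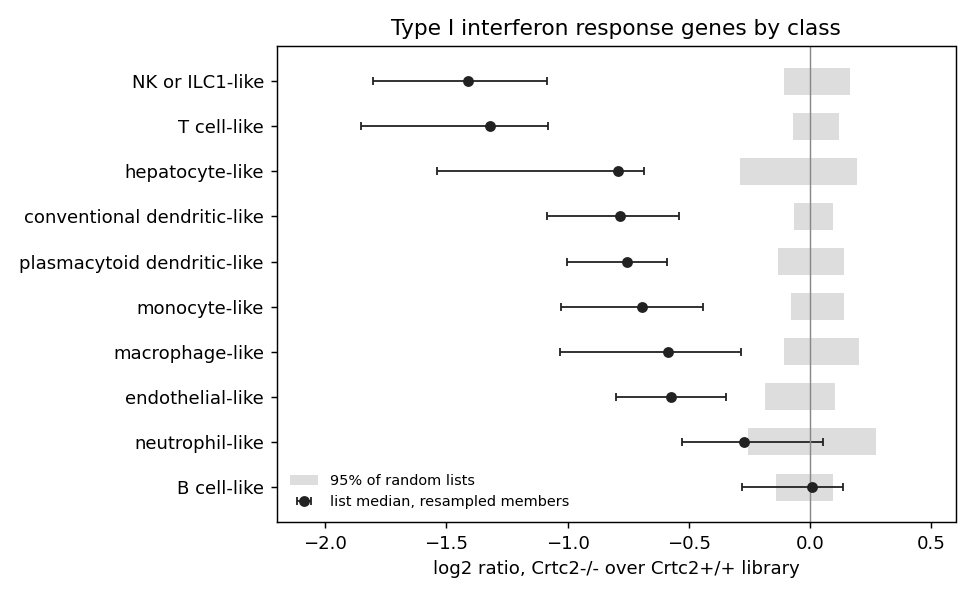
Median log2 ratio of type I interferon response genes, Crtc2-/- over Crtc2+/+ (x axis), per class. Points are list medians with 95% limits from resampling members, and grey bars span the central 95% of matched random lists. The medians ran from -1.41 in NK or ILC1-like cells to 0.01 in B cell-like cells.

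Genes that respond to interferon gamma were lower in the same lymphoid classes. In T cell-like cells all 18 measured members were below 0 (median -0.56), including the GTPase genes Iigp1 (148 and 42.1 CPM) and Igtp (159 and 68.7 CPM), while Ifng itself was higher. In NK or ILC1-like cells the median was -0.61 (15 of 16 below 0). In neutrophil-like cells it was 0.60 (12 of 15 above 0), with Gbp2 at 38.8 and 186 and Gbp5 at 35.3 and 121 CPM. Over the 10 compared classes this list was below 0 in 6, but in hepatocyte-like cells (-0.24) it was 0.17 when each library was clustered on its own, -0.65 in cluster 21 and -0.41 with a pseudocount of 1 CPM. Cytosolic DNA sensing genes had medians from -0.30 in hepatocyte-like to 0.11 in neutrophil-like cells, and the hepatocyte-like value was 0.61 when each library was clustered on its own. Their member Cxcl10, a chemokine induced by interferons, was at 210.1 and 46.6 CPM in T cell-like, 438 and 12.8 in NK or ILC1-like and 441 and 119.7 in macrophage-like cells, and at 304 and 666 in neutrophil-like cells. Cgas, which encodes the DNA sensor, was at 19.9 and 11.2 CPM in T cell-like cells. MHC class I presentation genes ranged from -0.21 in NK or ILC1-like to 0.35 in neutrophil-like cells. In T cell-like cells their median was -0.19, with Tapbp at 187 and 136 and H2-T23 at 289 and 218 CPM.

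Macrophage-like cells of the Crtc2-/- library carried transcripts of resident Kupffer cells, the macrophages of liver sinusoids, at much higher levels. Cd5l was at 46.2 (44.3 to 48.2) and 2030.4 (2006 to 2055) CPM (log2 ratio 5.18), and the complement receptor gene Vsig4 at 9.21 (8.35 to 10.1) and 443 (432 to 455) CPM (4.56). The iron exporter gene Slc40a1, Fcna and Clec4f were at 31.1 and 877, 2.86 and 208 and 11.9 and 320.3 CPM. Pmepa1, a target of TGF-beta signalling, was at 737 (729 to 745) and 11.9 (10.1 to 13.9) CPM (-5.09). Lhfpl2, Tnfsf13b (which encodes the B cell survival factor BAFF), Dach1 and Stard13 were at 177 and 4.62, 197 and 9.16, 185 and 8.71 and 139.9 and 5.15 CPM. All 12 Kupffer cell genes were above 0 (median 3.30, percentile 100). Several of them, such as Cd5l, Vsig4 and Clec4f, are also among the markers that named the class, and 66.4% of Crtc2-/- macrophage-like cells were in cluster 8 against 57.9% of Crtc2+/+ cells in cluster 0. Inside the 3 clusters shared by both libraries (669 and 762 cells) the Kupffer median was 2.51, the Cd5l log2 ratio 3.35 and the Pmepa1 log2 ratio -4.74. Those pooled values still carry cluster make-up, since 366 of the 669 Crtc2+/+ cells were in cluster 15 and 563 of the 762 Crtc2-/- cells in cluster 8. Within clusters 8, 15 and 24 the Kupffer medians were 1.37, 1.71 and 2.30 (12, 5 and 10 genes measured), and over all 6 macrophage-like clusters they ran from 0.10 to 2.57. The list was also above 0 and outside the random range in the other 8 classes where it was measured, from 0.30 in B cell-like to 1.11 in neutrophil-like cells, where RNA from other cells may be its source. Cd5l lies near Crtc2 on chromosome 3 (87357881 to 87371073, GRCm38), and strain variants around the targeted gene were not examined.

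Macrophage-like cells of the Crtc2-/- library had less Cd74 and H2-Ab1 and more Cxcl2, Il1a, Il18 and Lpl. MHC class II presentation genes differed in both directions, with a median of -0.30 (-0.94 to 0.38 by resampling members; percentile 0.260; 7 of 12 below 0) that was -0.90 with unnamed cells counted as macrophage-like. Cd74 was at 22210.1 and 10218, H2-Ab1 at 6921 and 3599 and the costimulatory gene Cd80 at 16.7 and 44.98 CPM. Inflammatory cytokine and chemokine genes had a median of 0.32 (percentile 99.7; 11 of 16 above 0), with Cxcl2 at 61.04 and 292, Il1a at 17.4 and 93.5 and Il18 at 54.9 and 224 CPM. In shared clusters that median was -0.13. Lipid-associated macrophage genes differed in both directions (median 0.37, percentile 99.8; 9 of 15 above 0), with medians of 0.19 in shared clusters and 0.66 with called doublets kept. Lpl, which encodes lipoprotein lipase, was at 173 and 642 and Fabp5 at 21.2 and 108 CPM, whereas Trem2 was at 254 and 69.2 and Cd63 at 917 and 272 CPM. Genes of immune suppression by myeloid cells had a median of 0.60 (percentile 100; 8 of 9 above 0). It was 0.38 in shared clusters, 0.36 with at least 1000 UMIs and 1.23 with a pseudocount of 1 CPM. The mannose receptor gene Mrc1 was at 146 and 549, the PD-L1 gene Cd274 at 60.8 and 128 and Stab1 at 200.1 and 60.7 CPM. Hepatocyte transcripts in this class had a median of 0.75.

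Monocyte-like cells of the Crtc2-/- library expressed more Saa3, an acute phase apolipoprotein gene, at 15.3 (12.6 to 18.3) and 135 (127 to 143) CPM (log2 ratio 2.52). Smpdl3b, the coagulation factor X gene F10, the purine metabolism gene Gda and Cdc42ep2 were at 34.5 and 113, 66.01 and 186, 186 and 483 and 16.2 and 51.4 CPM. Lower were Lhfpl2, at 53.5 (48.4 to 58.8) and 3.24 (2.16 to 4.69) CPM (-2.26), the integrin gene Itga6 (83.96 and 9.61 CPM) and Olfml3 (53.2 and 3.48 CPM). The chemokine gene Ccl12 and Cd72 were at 72.9 and 11.8 and 176 and 41.2 CPM. Lhfpl2 was also lower in macrophage-like cells, at 177 and 4.62 CPM. The macrophage gene C1qa was seen in 65.2% and 33.2% of monocyte-like cells, at 1610 and 583 CPM. Macrophage transcripts in this class may therefore account for some of the lower genes, which was not tested. Of the Crtc2+/+ monocyte-like cells 72.6% were in cluster 3, and of the Crtc2-/- cells 53.7% were in cluster 7.

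The B cell-like class of the Crtc2-/- library contained transcripts of antibody-secreting cells. Jchain, which encodes the joining chain of secreted IgA and IgM, had 1 UMI in the Crtc2+/+ and 24975 UMIs in the Crtc2-/- library, a ratio of 8896 (1597 to 351394), and was seen in 6.50% of Crtc2-/- cells. In the other Crtc2-/- classes Jchain was seen in 4.20% (T cell-like) to 10.4% (macrophage-like) of cells, so that share does not show which cells express it. At similar shares, Crtc2-/- monocyte-like cells (7.76%) held 81 Jchain UMIs and endothelial-like cells (6.96%) 45. The B cell-like cells with Jchain thus carried far more of it. Macrophage-like and T cell-like cells held 4582 and 1065 UMIs. The IgA heavy chain gene Igha was at 6.66 (3.55 to 11.4) and 2734 (2691 to 2778) CPM (log2 ratio 7.36) and the kappa light chain gene Igkc at 8623 and 47138 CPM. Tent5c and Txndc5, a disulfide isomerase gene of the secretory pathway, were at 5.13 and 51.1 and 72.3 and 291 CPM. Endoplasmic reticulum stress genes had a median of 0.68 in this class (percentile 100; 9 of 11 above 0), with Xbp1 at 29.7 and 132 and Hsp90b1 at 176 and 581 CPM. That median was 0.21 as a mean of per-cell CPM, where cells of high RNA content weigh no more than others. Lower in the Crtc2-/- library were Plcxd2, at 66.6 (55.7 to 79.1) and 19.2 (15.7 to 23.2) CPM (-1.39), Vps37b (328 and 150.3 CPM), Cecr2 (83.6 and 34.9 CPM), and the early response genes Fosb (92.8 and 41.4 CPM) and Nr4a1 (241 and 122 CPM). Cluster 2 held most B cell-like cells of both libraries (60.6% and 68.9%).

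In hepatocyte-like cells, Fabp5, Grip1, Akr1c18, Cyp2a4 and Tspan8 had the highest Crtc2-/- to Crtc2+/+ ratios. Fabp5, a fatty acid-binding protein gene, was at 11.6 (7.76 to 16.6) and 791 (759 to 824) CPM (log2 ratio 5.21), and Akr1c18, an aldo-keto reductase gene, at 11.98 (8.08 to 17.1) and 617 (589 to 646) CPM (4.83). Grip1, the cytochrome gene Cyp2a4 and the tetraspanin gene Tspan8 were at 15.97 and 751, 25.96 and 941 and 22.8 and 848 CPM. Kcnip4 had 383 UMIs in the Crtc2+/+ and 0 in the Crtc2-/- library, at least 150.1-fold lower against a floor of 3 counts over the class, and Brinp3 had 351 and 0, at least 138-fold lower. Csmd1 had 435 and 3 UMIs, a ratio of 0.00587 (0.00121 to 0.0173). The potassium channel gene Kcnh7 and the growth factor gene Mdk were at 256 and 2.04 and 204 and 4.76 CPM. Median depth in this class was 6356 and 11247 UMIs and the median mitochondrial share 4.98% and 1.33%. Different clusters held these cells: cluster 26 had 152 Crtc2+/+ and 0 Crtc2-/- cells, cluster 29 had 1 and 92, and cluster 21 had 171 and 136. The most enriched genes of cluster 26 held 3 hepatocyte markers. They also held Spp1, Clu, Tm4sf4, Krt18 and Krt8, which were among those of the cholangiocyte-like cluster 31. Cluster 29 shared Clu and Tm4sf4 with cluster 31. Whole-class values of hepatocyte-like cells, here and elsewhere, may therefore carry different cell types, which was not tested. In cluster 21 alone, whose median depth was 2041 and 3126.5 UMIs, the log2 ratios were 5.90 for Fabp5, 3.92 for Akr1c18 and 3.19 for Tspan8. They were 0.27 for Grip1, 1.22 for Cyp2a4, -1.11 for Kcnh7, -0.58 for Mdk, -0.87 for Brinp3, 0.14 for Csmd1 and 0 for Kcnip4. The mean Scrublet score was 0.125 in cluster 29, against 0.0639 in cluster 21 and 0.0883 in cluster 26. The median depth of Crtc2-/- cells in cluster 29 was 19224.5 UMIs, and missed doublets stay open for that cluster.

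Cholesterol synthesis genes were higher together in hepatocyte-like cells of the Crtc2-/- library (median 1.11, percentile 100; 15 of 15 above 0). Over the 10 compared classes the list was above 0 in 9 and outside the random range in 6, with the highest median in hepatocyte-like cells. In hepatocyte-like cells Idi1 was at 11.98 and 145, Hmgcs1 at 21.97 and 204 and Fdps at 58.3 and 319.7 CPM, and the median in cluster 21 was 1.16. Mitochondrially encoded transcripts were lower in the same cells (-1.23 in the class and -2.38 in cluster 21). CREB and CRTC target genes were divided (median 0.03, percentile 70.8; 8 of 16 above 0): the early response genes Fos and Fosb were at 97.8 and 398 and 37.5 and 164 CPM, Pck1, a gluconeogenic enzyme gene, at 38.7 and 89.001, and G6pc, which encodes glucose-6-phosphatase, at 19.97 and 3.06 CPM. Over the 10 classes this list was above 0 in 7 and outside the random range, on either side, in 6. It ran from -0.83 in neutrophil-like to 0.61 in plasmacytoid dendritic-like cells, and in T cell-like cells it was 0.49. In cluster 21 it was -0.14. Gluconeogenesis genes were likewise divided (median 0.07, percentile 75.2; 5 of 9 above 0), with Gpt at 17.6 and 54.01 and Fbp1 at 122 and 291 CPM, and a median of 0.82 in cluster 21. Fatty acid synthesis genes (median 0.12, percentile 88.8; 8 of 13 above 0) included Lpin1 at 18.8 and 68.6 and Scd1 at 87.5 and 157 CPM, with a median of 0.42 in cluster 21. Lipid droplet and steatosis genes (median 0.04, percentile 69.1; 4 of 7 above 0) included Plin2 at 252 and 748 and Cd36 at 177 and 38.4 CPM, and had a median of 1.13 in cluster 21. Fatty acid oxidation and PPAR alpha targets (median 0.10, percentile 73.5; 9 of 13 above 0) included Pdk4 at 12.8 and 123 and Acadm at 167 and 255 CPM. Bile acid synthesis and transport genes (median 0.03, percentile 75.4; 5 of 9 above 0) included the repressor gene Nr0b2 at 4.39 and 54.7 and Cyp7b1 at 57.9 and 9.85 CPM, with a median of -0.22 in cluster 21.

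Acute phase genes were higher in hepatocyte-like cells of the Crtc2-/- library (median 0.96, percentile 100; 13 of 14 above 0), with Orm1 at 64.3 and 499, Serpina3n at 16.8 and 164 and Itih3 at 35.5 and 241 CPM, and a median of 1.07 in cluster 21. Over the 8 classes where this list was measured it was above 0 in 8 and outside the random range in 7, with the highest median in hepatocyte-like cells. All 18 p53 targets were above 0 (median 0.89, percentile 100), including Btg2 (161 and 631 CPM), Gdf15 (53.5 and 233 CPM) and Mdm2, the negative regulator of p53 (73.5 and 289.8 CPM), but the median was -0.06 in cluster 21. Liver tumour and fetal genes were divided (median 0.92, percentile 99.99; 6 of 11 above 0). Afp, which encodes alpha-fetoprotein, was at 11.2 and 293, Ly6d at 204 and 2914 and Spink1 at 659 and 213 CPM, and the median was -0.12 in cluster 21 and 0.46 as a mean of per-cell CPM. Cytochrome P450 genes of mature hepatocytes (median 0.78, percentile 99.98; 7 of 9 above 0) included Cyp2d26 at 38.3 and 115 and Cyp2a5 at 309.9 and 79.5 CPM. Cyp2e1 had 0 and 190 UMIs, at least 53.9-fold higher in the Crtc2-/- library. The P450 median was -0.14 when each library was clustered on its own, 0.55 in cluster 21, 1.17 with a pseudocount of 1 CPM and 1.24 with members of at least 100 UMIs. Wnt and beta-catenin liver targets had 4 measured members (median 1.35, percentile 99.97; 3 of 4 above 0), with Oat at 10.8 and 19.7 and Glul, which encodes glutamine synthetase, at 45.1 and 42.1 CPM. The median was 0.32 with called doublets kept, 2.22 in cluster 21, 2.19 with members of at least 100 UMIs and 2.54 with a pseudocount of 1 CPM. NRF2 targets (median -0.05, percentile 30.4; 5 of 12 above 0) included the glutathione transferase genes Gsta1 (478 and 121 CPM) and Gsta2 (315 and 24.5 CPM) and the haem oxygenase gene Hmox1 (22.8 and 87.6 CPM), with a median of -0.65 in cluster 21.

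Endothelial-like cells of the Crtc2-/- library carried more sinusoidal and fewer capillary transcripts. All 12 sinusoidal endothelial identity genes were above 0 (median 1.70, percentile 100), with Clec4g at 271 and 1262, the scavenger receptor gene Stab2 at 623 and 2551 and Dnase1l3 at 242 and 1041 CPM. Over the 9 classes where this list was measured it was above 0 in 9 and outside the random range in 6, with the highest median in endothelial-like cells. RNA from other cells may be its source in the other classes, which was not tested. Capillary and tumour endothelium genes had a median of -1.13 (percentile 0; 9 of 12 below 0), with Vwa1 at 113 and 11.3, Aplnr at 126 and 15.1 and its ligand gene Apln at 201 and 33.8 CPM. The capillary list was above 0 in 5 of the 6 classes where it was measured, and below 0 in endothelial-like cells only. The venular gene Ackr1 was at 6.66 and 73.5 CPM. The clusters differed between libraries: 75.4% of Crtc2+/+ cells were in cluster 20 and 77.6% of Crtc2-/- cells in cluster 12. Within cluster 20 the sinusoidal median was 2.05 and the capillary median -0.75, and within cluster 12 they were -0.14 and 0.55. No cluster was mesenchymal-like, so extracellular matrix genes were read in endothelial-like cells, a choice of class and of the genes named that was made after seeing the data. Their median was -1.12 (percentile 0; 10 of 12 below 0), with Col1a1 at 123 and 11.6, Col3a1 at 162 and 33.2 and Dcn at 16.7 and 34.6 CPM. Of the 5 classes where this list was measured, 4 had medians above 0, up to 0.89 in hepatocyte-like cells (percentile 99.74). The list was not read within clusters 12 and 20.

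DNA repair genes, which the series title ties to CRTC2 through DNA-dependent protein kinase, were read in all compared classes. Non-homologous end joining genes had medians from -0.11 in B cell-like to 0.57 in neutrophil-like cells, and none of the 10 classes lay outside the central 95% of random lists. The neutrophil-like value rested on 5 members, such as Xrcc4 at 24.7 and 45.2 CPM, and was 0.16 with members of at least 100 UMIs. In T cell-like cells the median was -0.05 (9 of 15 below 0), with Xrcc5, the Ku80 gene, at 39.2 and 32.1 and Dclre1c, the Artemis gene, at 28.96 and 38.5 CPM. In hepatocyte-like cells it was -0.08, with Paxx at 28.8 and 13.9 and Xrcc4 at 27.6 and 45.2 CPM, but 0.40 in cluster 21 and 0.87 when each library was clustered on its own. Prkdc was at 11.98 (8.08 to 17.1) and 16.6 (12.3 to 22.01) CPM in hepatocyte-like and at 25.7 (19.3 to 33.5) and 39.2 (34.5 to 44.3) CPM in endothelial-like cells. Homologous recombination genes had medians from -0.20 in hepatocyte-like to 0.22 in plasmacytoid dendritic-like cells. Of 9 classes, 2 lay outside the random range, conventional dendritic-like below (-0.10, percentile 1.98) and T cell-like above (0.10, percentile 97.6). Rbbp8, the CtIP gene, was at 45.2 and 69.7 CPM in T cell-like and 48.3 and 20.04 in hepatocyte-like cells, and Atm at 77.3 and 55.4 CPM in T cell-like cells. The homologous recombination median in T cell-like cells was -0.16 when each library was clustered on its own. CRTC and CREB family genes and their regulators had medians from -0.18 in B cell-like to 0.14 in plasmacytoid dendritic-like cells. Crem, a CREB target that encodes a repressor, was at 64.5 and 108 CPM in T cell-like and 133 and 69.4 in B cell-like cells, and the kinase gene Sik1 at 58.8 and 33.7 in macrophage-like cells.

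Proliferation genes ranged from -0.26 in endothelial-like to 1.95 in neutrophil-like cells. In neutrophil-like cells Ube2c had 2 and 171 UMIs, a ratio of 16.1 (4.39 to 134). The list median there was 0.75 as a mean of per-cell CPM, 0.54 at resolution 2 and 3.57 with a pseudocount of 1 CPM. In T cell-like cells the median was 0.37, with Birc5 at 34.2 and 60.4 and Mcm6 at 62.2 and 99.8 CPM, but -0.99 when each library was clustered on its own. In macrophage-like cells it was 0.67 over all clusters, with Ube2c at 46.9 and 154 CPM, and -0.97 in shared clusters. The shared value pools clusters of different make-up: cluster 15, the cycling one, held 366 of the 669 Crtc2+/+ but 111 of the 762 Crtc2-/- cells. Over the whole class, thinned shares of cells with a Mki67 UMI were 3.47% and 8.16%. In NK or ILC1-like cells it was 0.47, with Stmn1 at 52.1 and 130.03 CPM, and -0.42 when each library was clustered on its own. Endoplasmic reticulum stress genes ranged from -0.35 in neutrophil-like to 0.68 in B cell-like cells. In hepatocyte-like cells they had a median of 0.64, with Xbp1 at 129.8 and 421 and Ddit3 at 67.9 and 16.6 CPM, and 0.11 in cluster 21.

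Transcripts that mark handling and free RNA also differed. Tissue dissociation and heat shock genes ranged from -0.21 in neutrophil-like to 0.64 in endothelial-like cells, where Egr1 was at 80.9 and 249 and Fos at 164 and 446 CPM. As means of per-cell CPM these ends were -0.02 and 0.40, and the neutrophil-like median was 0.07 at resolution 2 and the endothelial-like median 0.32 with called doublets kept. In hepatocyte-like cells their median was 0.54, with Btg2 at 161 and 631 CPM, but -0.06 in cluster 21 and 2.14 when each library was clustered on its own. In macrophage-like cells it was 0.24, and -0.70 in shared clusters. In B cell-like cells Fos was at 311 and 111 and Junb at 652 and 269 CPM. Genes of the hepatocyte free RNA list were above 0 by their median in 10 of 10 classes, from 0.29 in T cell-like to 1.55 in NK or ILC1-like cells. With a pseudocount of 1 CPM these ends were 0.98 and 3.32, and with members of at least 100 UMIs the neutrophil-like median was -0.32. Apoa1, an apolipoprotein gene of hepatocytes chosen here after its values were seen, was at 2.93 and 14.2 CPM in T cell-like, 4.10 and 30.9 in B cell-like and 1236 and 10099.9 in hepatocyte-like cells. Mitochondrially encoded transcripts ranged from -1.23 in hepatocyte-like to 0.42 in macrophage-like cells. In hepatocyte-like cells mt-Nd4 was at 5952 and 1675 CPM. Sex-linked genes ranged from -0.12 in B cell-like to 0.37 in hepatocyte-like cells, inside the random range in all 10 compared classes, and the Y-linked Ddx3y was detected in both libraries (97.1 and 114 CPM in T cell-like cells).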

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

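The tests of dissociation stress in the unnamed cells, of single clusters in T cell-like cells and of the animal or tumour sampled were set before their values were seen. The tests of doublets, of a library-wide difference or loss, of free RNA and of early response genes were chosen after the values had been seen.

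Clusters left without a class name held 978 cells of the Crtc2-/- library and 0 of 9327 cells (0% to 0.0395%) of the Crtc2+/+ library. They stand outside the comparisons of named classes. They were cluster 6 (917 cells) and cluster 30 (61 cells), where macrophage markers had the highest score. They stayed unnamed because the monocyte marker Cd300e, and no macrophage marker, was among their 10 most enriched genes. Counted as macrophage-like, they put that class at 49.9% and 20.5% of kept cells. In these cells, Crtc2-/- monocyte-like and Crtc2-/- macrophage-like cells, Fcgr4, which encodes a low-affinity Fc receptor of patrolling monocytes, was at 3722, 159 and 517 CPM, and Cd300e at 760.0, 57.9 and 109, but Ace and Treml4, markers of the same monocytes, were at 4.24, 156 and 3.79 and at 94.4, 169 and 206 CPM. Ly6c2, a marker of classical monocytes, was at 4.803, 468 and 35.2 CPM, Ccr2 at 18.4, 789.7 and 140.0, C1qa at 2301, 583 and 4379.9 and Csf1r at 243, 478 and 605, all genes chosen after their values were seen. MHC class II presentation genes were lower than in Crtc2-/- monocyte-like and macrophage-like cells (medians -2.67 and -2.47), as were type I interferon response genes (-0.90 and -1.11), while mitochondrially encoded genes (0.73 and 0.26) and hepatocyte free RNA (0.64 and 0.31) were higher. Proliferation genes were higher than in Crtc2-/- monocyte-like cells (1.51, 1.12 to 2.03) but lower than in Crtc2-/- macrophage-like cells (-0.71, -1.02 to -0.54).

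Doublets would raise the Scrublet score, but the median score of unnamed cells was 0.712 (0.676 to 0.753) times that of other kept cells of the library, which speaks against doublets of 2 cell types for most of them, though the mean score was 0.0286 in cluster 6 and 0.0803 in cluster 30, so doublets stay open for the latter. A technical difference that sets all cells of the libraries apart would also split lymphoid cells by library, but 100% (99.94 to 100) of 6561 T cell-like, NK or ILC1-like and B cell-like cells were in clusters with at least 10% of each library. So were all 848 and 953 monocyte-like cells, but only 669 of 4651 and 762 of 848 macrophage-like cells, so a difference limited to some classes stays open. Dissociation stress would raise the dissociation and heat shock genes, but their median in unnamed over Crtc2-/- monocyte-like cells was -0.53 (-1.17 to -0.07). For cluster 6, these values suggest a myeloid population seen in the Crtc2-/- library alone, and whether it belongs to the genotype or to the animal or tumour sampled was not tested.

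The lower type I interferon response genes in T cell-like cells of the Crtc2-/- library had a median log2 ratio of -1.32. Without cluster 23, the T cell-like cluster richest in these transcripts and held mostly by the Crtc2+/+ library, the median was -1.03 (-1.29 to -0.68), and after subtraction of free RNA it was -1.34 (-1.93 to -1.07), so neither explains the difference alone. A library-wide loss of these transcripts would show in B cell-like cells, where the median was 0.00709 (-0.280 to 0.134). These values are consistent with a lower interferon response of T cell-like cells in this tumour sample. With 1 library per genotype, the animal or tumour sampled cannot be separated from Crtc2, and that biological difference stays untested.

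The higher exhaustion and activation genes in T cell-like cells of the Crtc2-/- library had a median log2 ratio of 1.498. Without cluster 18, the cluster richest in Pdcd1 and held mostly by the Crtc2-/- library, the median was 1.31 (0.86 to 1.68), so that cluster alone does not explain it. Without the 5 members that also respond early to cell handling (Nr4a2, Rgs16, Tnfrsf9, Ccl3 and Ccl4) the median of the other 9 was 0.95 (0.28 to 1.71), with Lag3, Havcr2, Ctla4 and Tigit among them. Dissociation and heat shock genes were higher in T cell-like cells as well (median 0.38), and the limits are wide, so a part played by early response during dissociation stays open. Whether loss of Crtc2 in T cells or in other cells could produce the rest was not tested.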

How the results depend on the processing

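Most values stayed inside the counting or member-resampling interval of the reported value, which can include 0. That held for 82 of 98 class-share values, 1762 of 1897 gene list values, 930 of 1145 gene values and 101 of 117 T cell state values. These counts include values that a setting could not change, so they overstate stability. Counting unnamed cells as macrophage-like left 9 other shares as they were, and free RNA was not subtracted in hepatocyte-like cells. The sign differed in 4 class-share, 191 gene list, 33 gene and 10 T cell state values, and in 23 of these 238 the reported interval left out 0. Those 23 follow as log2 ratios, with shifts of the main results, and the cause was not tested unless named. The macrophage-like share was -2.49 at resolution 2, -2.55 with a mitochondrial limit of 10% and -2.55 with doublets kept. Proliferation in macrophage-like cells was -0.0980 at resolution 2, -0.0792 with the 10% limit, -0.83 with each library clustered on its own and -0.97 in shared clusters, of which the cycling cluster 15 held 366 of 669 Crtc2+/+ but 111 of 762 Crtc2-/- cells. Mitochondrially encoded genes in neutrophil-like cells were 0.0693 at resolution 2 and 0.0674 as means of per-cell CPM, and by such means -0.0823 in conventional dendritic-like cells, while non-homologous end joining in hepatocyte-like cells was 0.0805. Homologous recombination in endothelial-like cells was -0.0291 with a 50% limit and -0.00785 with at least 1000 UMIs, where the monocyte-like share was 0.46. With each library clustered on its own, the hepatocyte-like share was 0.57, the conventional dendritic-like share 0.71, non-homologous end joining in hepatocyte-like cells 0.87, Csmd1 0.14 and Creb1 1.03, and in T cell-like cells homologous recombination -0.16 and proliferation -0.99. With list members of at least 100 UMIs, homologous recombination was 0.0388 in conventional dendritic-like and hepatocyte free RNA -0.32 in neutrophil-like cells. A pseudocount of 1 CPM, which by construction spreads low values, put Crtc2 at -0.72 in hepatocyte-like, -0.57 in monocyte-like, -0.98 in conventional dendritic-like, -0.96 in T cell-like, -1.36 in NK or ILC1-like and -1.51 in B cell-like cells. The Pdcd1 difference of 8.82 points was 12.999 at 2000 UMIs and 18.1 without thinning, since deeper cells show more genes. The other settings were chosen after seeing the data. Without macrophage-like and unnamed cells in the denominator, which by construction lowers every ratio, shares were -1.10 for hepatocyte-like, 0.70 for endothelial-like, -0.43 for monocyte-like, 0.26 for conventional dendritic-like, 1.30 for plasmacytoid dendritic-like, 1.42 for neutrophil-like, -0.22 for T cell-like, -0.38 for NK or ILC1-like and 0.52 for B cell-like cells. In shared clusters of hepatocyte-like cells, p53 targets were -0.0568, non-homologous end joining 0.40, dissociation and heat shock -0.0568, Csmd1 0.14 and Crtc2 -0.87, and in those of macrophage-like cells type I interferon response was -0.19 and Crtc2 -0.15. With unnamed cells counted as macrophage-like, the share was -1.28, type I interferon response -0.98, MHC class II presentation -0.90, interferon gamma response -0.28 and Prkdc 0.11. No class was erythroid-like, so the denominator planned without such cells left out hepatocyte-like cells only. Depth limits Crtc2 in small classes, with 5 and 8 UMIs in neutrophil-like, 10 and 4 in NK or ILC1-like and 17 and 11 in hepatocyte-like cells. No paired analysis was possible because each genotype had 1 library.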

Other observations

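Several genes differed in the same direction in most classes, and all genes of this part were chosen after their values were seen. C1qa, which encodes a complement subunit made by macrophages, was at least 2-fold lower in the Crtc2-/- library in 7 of 10 classes, Cxcl10 in 7 of 10 and Pmepa1 in 7 of 9. C1qa was at 6426 and 4380 CPM in macrophage-like but 107 and 34.2 CPM in T cell-like cells, and Pmepa1 at 737 and 11.9 CPM in macrophage-like cells. Macrophage-like cells made up 49.9% and 9.53% of the libraries. Their RNA may be the source of C1qa and Pmepa1 in other classes, which was not tested. The hepatocyte gene Serpina1b was at least 2-fold higher in 10 of 10 classes and Apoa1 in 8 of 10. Summed hepatocyte markers were at 1489 and 3583 CPM of the whole library, hepatocyte-like cells included, and at 74.7 and 123 CPM in T cell-like cells, where the estimated free RNA fraction was 5.02% and 3.44%. Gm47283, annotated on chromosome Y (90784738 to 90816464, GRCm38), was at least 2-fold higher in 8 of 9 classes, at 15.5 and 84.5 CPM in T cell-like and 12.8 and 89.1 CPM in B cell-like cells. The sex-linked list lay inside the random range in all 10 compared classes, so this gene alone does not show a difference in sex or in Y-linked transcripts.

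Transcripts of erythroid and antibody-secreting cells appeared in other classes of the Crtc2-/- library. The haemoglobin gene Hbb-bs was at 0.371 and 1591 CPM in macrophage-like and 3.33 and 2065 CPM in endothelial-like cells. It was seen in 14.5% and 7.98% of these Crtc2-/- cells, with 21016 and 13548 UMIs, so its CPM is not a level of the whole class. In Crtc2-/- monocyte-like cells it was seen in 5.67% of cells, with 60 UMIs. Jchain was at 1.27 and 347 CPM and Igha at 0.764 and 502 CPM in macrophage-like cells, seen in 10.4% and 9.67% of the Crtc2-/- cells. Tmem119 was at 118 and 7.80 CPM in macrophage-like cells.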
